A study of Caenorhabditis elegans with 18 samples.

How the data were processed

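RNA from whole Caenorhabditis elegans of 3 genotypes was sequenced: wild type (N2), daf-10(e1387) and che-3(e1124). Synchronized larvae were grown on Escherichia coli OP50, the usual laboratory food, at 20 °C until the fourth larval stage. They were then kept for 24 h at 25 °C either on OP50 or on Pseudomonas aeruginosa PA14, a pathogen of worms. Each of the 6 combinations of genotype and food had 3 libraries, 18 in all. The labels do not say whether the 3 replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

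The submitters' notes name HISAT2 2.0.4, HTSeq 0.9.1 and DESeq 1.18.0, without saying what each was used for. The deposited table gives raw read counts per gene in each library, FPKM per gene in each library, and the authors' own 7 comparisons. In the deposited FPKM values each count was divided by gene length and by the median-ratio size factor times the geometric mean of the 18 totals. That was checked on the table and held in every library for all genes with more than 50 counts there, within a relative tolerance of 1e-06. For each comparison the authors also gave a log2 fold change, a p-value and an adjusted p-value. Another 14 columns, with a value per group in each of the authors' comparisons, were not used here. The other deposited columns hold gene coordinates and gene length. The genome build is not given in the sources used here; 46817 of the 46904 gene identifiers matched the Ensembl release 115 annotation of WBcel235, and all matched genes overlapped their position there. Coordinates below are those of the deposited table.

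Total counts per library ranged from 18550309 to 21631610. Genes with a mean FPKM of at least 1 over all 18 libraries were tested, 11499 of 46904, and these held 99.7% of all counts. The tested genes include 150 annotated piRNA genes with a median of 0.61 counts per library, which owe their FPKM to a length of 21 bases.

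Differences between groups were tested with edgeR 4.0.16 (R 4.3.3) on the counts: TMM scaling, 1 mean per group, a quasi-likelihood F test for each contrast, and the spread estimated from all 18 libraries. The common biological coefficient of variation was 0.136. A gene is called higher or lower when its Benjamini-Hochberg adjusted p is under 0.05. Every adjusted p for a gene is from this edgeR fit unless another tool or the fit without a filter is named. Before the data were examined, the planned test was limma on log2(FPKM + 1), because the deposited table was named as FPKM; when counts were found in it, a count model took its place and limma became an alternative. There were 11 comparisons: infection within each genotype, each mutant against wild type on each food, the difference between each mutant's response to infection and that of wild type (an interaction), and daf-10 against che-3 on each food. Fold changes are on the log2 scale, with the standard error of the fit after ±; levels are mean FPKM ± SD of 3 libraries.

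Lists of genes were also fixed in advance: p38 MAPK-dependent immune effectors, PMK-1-independent infection response genes, C-type lectins, lysozymes and saposin-like proteins, caenacins with antimicrobial nlp peptides and abf, the pals family, DAF-16 class I targets, cytochrome P450, UGT and GST enzymes, heat shock proteins, the hypoxia and hydrogen sulfide response, fatty acid metabolism, vitellogenins, oocyte and eggshell, germline proliferation and meiosis, sperm, collagens, body wall muscle, intestine, pharynx, pan-neuronal genes, intraflagellar transport with BBS and transition zone, ciliated sensory neuron signalling, neuropeptides and insulin-like peptides, cytosolic ribosomal proteins, and mitochondrially encoded messenger RNAs. The 25 lists were tested against the other genes with camera (limma 3.58.1) on log2(FPKM + 1), a preset correlation between genes of 0.01, and Benjamini-Hochberg adjustment over the lists of each comparison. Every list call was repeated with a correlation estimated from the data. List members were also adjusted over the list alone. Of the lists on cilia, only 9 of 46 transport members and 6 of 27 signalling members were tested, since most were below the expression filter. The lists rest on general knowledge of the worm, not on these libraries, and whole worms express all of the tissue lists.

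Named genes were chosen by a rule set in advance. For each of the 7 comparisons with wild type or between foods, these were the 6 called genes with the largest positive and the 6 with the largest negative fold change, among genes whose FPKM ranges did not overlap and were above 0 in every library of both groups. For each interaction and each comparison of daf-10 with che-3, these were 3 and 3. Non-overlap was not applied to the interactions, which involve 4 groups. Genes described below as highest, lowest or most changed are so among the genes that this rule allows. Up to 4 called members of a list could be named, and daf-10, che-3, irg-1, irg-4, irg-5, T24B8.5, sod-3 and hsp-16.2 were named in advance. C50C3.15, snb-5, C50C3.1, unc-86, F58H1.2, R31.2, aman-2, and the propionate genes hach-1, ech-6 and alh-8 were chosen after their values were seen. For genes below the filter, and for the genes around unc-36 and osm-6, values are from a second edgeR fit without a filter, on all genes with a mean FPKM above 0. That fit has its own estimate of the spread, and its adjusted p-values are not comparable with those of the main fit. For unc-36 in che-3 on OP50 it gave an adjusted p of 1.8e-85, far below that of the main fit.

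Alternatives planned in advance were a pseudocount of 0.1 in limma, no expression filter, a filter at 5 FPKM, median-ratio size factors, the libraries of the compared groups alone, the replicate number as a block, limma without a mean-variance trend, a 2-fold limit as well, camera with an estimated correlation, on log2(FPKM + 0.1), on TMM-scaled log2 CPM and with the replicate block, and leaving out each library in turn. Total counts without scaling factors, edgeR's own count filter and DESeq2 1.42.0 were added after seeing the data, as were the list tests and the overlap of the mutants without che-3 PA14 replicate 1. On simulated data with the spread of these libraries, the wild-type infection contrast recovered 46.3%, 79.1% and 98.5% of genes changed 1.5-, 2- and 4-fold, with 7.5% false calls; the daf-10 interaction recovered 26.9%, 59.7% and 89.4%, with 5.6% false calls. Tables were prepared and drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.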

Results

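The 18 libraries cover wild-type, daf-10 and che-3 animals on OP50 or PA14, with 3 libraries in each of the 6 groups. daf-10 encodes a subunit of an intraflagellar transport complex and che-3 the heavy chain of the dynein that moves cargo back along the cilium; both mutants have defective sensory cilia. The comparisons address which genes differ between each mutant strain and wild type, and whether the response to infection does. No other allele and no rescued strain is among the samples. Effects of the mutation and of the strain background therefore cannot be told apart. Total counts per library were 18550309 to 21631610, and protein-coding genes held 98.5% to 99.14% of them.

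The transcripts of the mutated genes themselves were rare. daf-10 (WBGene00000906, chromosome IV, 9136933 to 9146210) had 0.189 ± 0.0469 FPKM in wild type on OP50, 0.163 ± 0.0238 in wild type on PA14, 0.212 ± 0.04 in daf-10 on OP50, 0.177 ± 0.0444 in daf-10 on PA14, 0.299 ± 0.102 in che-3 on OP50 and 0.301 ± 0.175 in che-3 on PA14. That corresponds to 7 to 35 counts per library, and no comparison called daf-10. che-3 (WBGene00000485, chromosome I, 8062059 to 8081671) had 0.125 ± 0.0224 FPKM in wild type on OP50 and 0.152 ± 0.0393 on PA14. It was higher in both mutants, at 0.485 ± 0.0939 and 0.394 ± 0.0461 in daf-10 and at 0.338 ± 0.0284 and 0.306 ± 0.165 in che-3, on OP50 and PA14 in turn. In replicate 1 of che-3 on PA14 it was not higher, at 0.125 FPKM against 0.118 to 0.195 in wild type and 0.447 and 0.344 in the other che-3 PA14 libraries. The log2 fold changes of che-3 against wild type were 1.94 ± 0.283 (adjusted p = 1.24e-08) in daf-10 and 1.41 ± 0.286 (8.26e-05) in che-3 on OP50, and 1.39 ± 0.282 (7.2e-05) and 1.02 ± 0.284 (0.00381) on PA14. Neither infection nor the interactions nor daf-10 against che-3 gave a call for che-3. Both genes were below the expression filter, so these values are from the fit without it, whose p-values are not comparable with those of the main fit.

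The first component of a principal component analysis held 48.6% of the variance and parted the foods; the next components held 14.2% and 7.6%. Replicate 1 of che-3 on PA14 had a value of -48.2 on the third component, against -15.1 to 19.9 for the other libraries. Its correlations with the other che-3 PA14 libraries were 0.97 and 0.971, against 0.988 between those and 0.984 to 0.992 within the other groups. Relative to the other che-3 PA14 libraries its medians were -1.46 for pharynx genes, -1.39 for heat shock proteins, -1.05 for the p38-dependent effectors, -0.89 for neuropeptides, -0.72 for caenacins and 0.66 for ribosomal proteins, on the log2 scale. No library was left out of the fit; some values below are also given without this library.

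**Figure D1:**
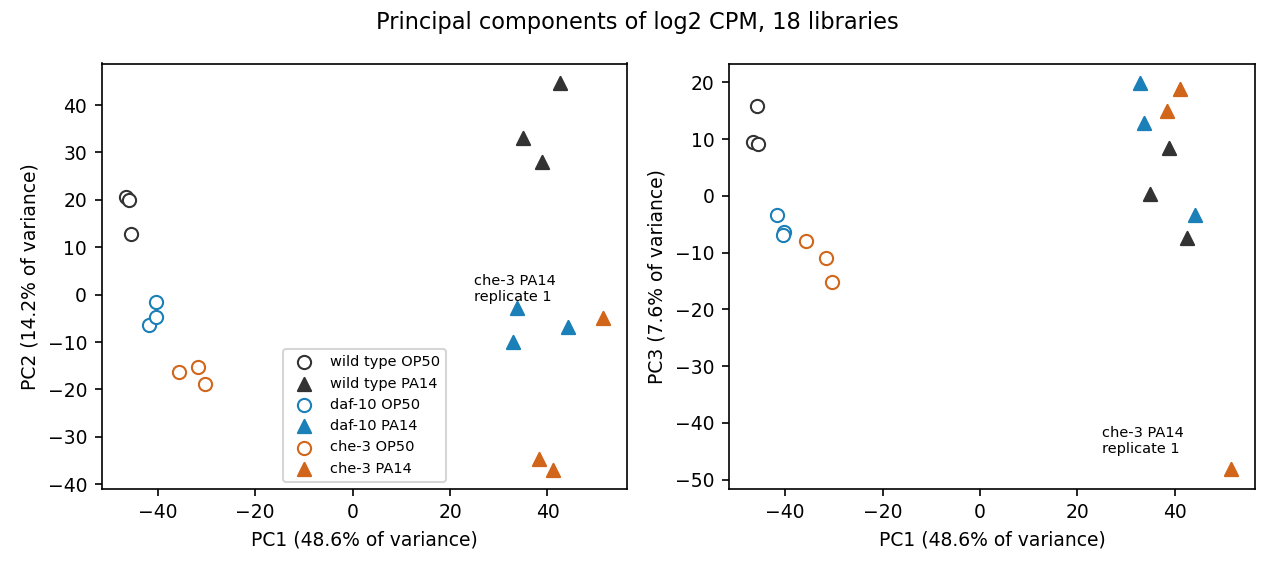
Principal components 1, 2 and 3 of TMM-scaled log2 CPM, a point per library, colored by genotype, with shape and fill by food. Component 1 parts the foods, and che-3 PA14 replicate 1 lies at -48.2 on component 3.

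Infection of wild type strongly induced p38-dependent effectors and PMK-1-independent infection response genes. Caenacins fell and C-type lectins split in both directions, as given below. Expression of acdh-1, which encodes an acyl-CoA dehydrogenase, was shut off. acdh-1 (WBGene00016943, chromosome I, 6497436 to 6499560) fell from 583 ± 64.8 to 0.326 ± 0.158 FPKM, a log2 fold change of -10.79 ± 0.20 (adjusted p = 2.13e-16). C32H11.9 (chromosome IV, 12935011 to 12936271) rose from 0.148 ± 0.15 to 110.2 ± 21.1 FPKM (9.56 ± 0.51, adjusted p = 2.25e-10), and its neighbor dod-21 (12936738 to 12937988) from 0.165 ± 0.14 to 118.8 ± 11.9 FPKM. irg-1, an infection response gene that does not need the p38 kinase PMK-1, rose from 0.251 ± 0.152 to 33.1 ± 6.78 FPKM. The other genes of the largest increases were B0024.4 (6.74), the C-type lectin gene clec-4 (6.72) and C49G7.12 (6.66). acdh-2 (-9.07), the acyl-CoA synthetase gene acs-2 (-6.99), C09B8.4 (-6.93), clec-218 (-4.81) and the propionate shunt gene hphd-1 (-4.74 ± 0.16, 215 ± 21.2 to 8.02 ± 0.462 FPKM) fell most. irg-5 rose by 4.06 ± 0.51, irg-4 by 2.33 ± 0.26 and T24B8.5 by 1.71 ± 0.24, whereas sod-3 (0.19, adjusted p = 0.727) and hsp-16.2 (-0.52, adjusted p = 0.534) did not pass. In all, 2419 genes were higher and 2355 lower on PA14 in wild type. With total counts in place of TMM the median of all genes moved by -0.145 and the split became 1499 higher and 3470 lower.

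Of the 13 tested p38 MAPK-dependent effectors, 13 were higher in infected wild type, also when adjusted over the list alone (median 2.33, camera adjusted p = 2.2e-10). With an estimated correlation between genes, 0 of the 12 list calls in infected wild type remained: adjusted p = 0.073 with an estimated correlation for the PMK-1-independent genes, 0.2 for the p38 effectors and 0.43 or more for the others. Among the p38 effectors dod-24 rose from 21 ± 1.57 to 342 ± 54.6 FPKM and clec-67 from 1.57 ± 0.325 to 23.3 ± 3.54. Of the 7 PMK-1-independent genes, 6 were higher and 1 did not pass, with 6 adjusted over the list alone (median 5.1, 4e-07). pgp-5, which encodes an ABC transporter, rose by 6.21 ± 0.20 and irg-2 by 5.1 ± 0.26. Of the 77 cytosolic ribosomal protein genes, 72 were higher, 0 lower and 5 did not pass, with 76 higher adjusted over the list alone (median 0.71, 4.7e-17). rpl-19 rose from 1963 ± 19.1 to 3654 ± 444 FPKM and rpl-39 by 1.19 ± 0.18. Of 67 collagens 3 were higher and 33 lower, 4 and 33 over the list alone (-0.77, 0.00023), and col-93 fell from 543 ± 93.5 to 48 ± 14.3 FPKM. Of 17 body wall muscle genes 12 were lower and 5 did not pass, 14 lower over the list alone (-0.48, 0.00019). Of 21 oocyte and eggshell genes 16 were lower, 19 over the list alone (-0.37, 7.5e-05), with oma-2 at -0.58 ± 0.12. Of 20 germline proliferation and meiosis genes 11 were higher, 13 over the list alone (0.28, 0.0014), with fbf-2 at 1.32 ± 0.23.

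Further lists called in infected wild type were the caenacins and antimicrobial peptides (9 of 25 lower and 0 higher, 1 higher and 11 lower over the list alone, median -0.94, adjusted p = 0.00073), the hypoxia and hydrogen sulfide response (6 of 9 lower, the same over the list alone, -0.86, 0.0012), the neuropeptides (5 higher and 22 lower of 88, 4 and 10 over the list alone, -0.72, 0.0041), the pals family (3 of 9 higher, 3 over the list alone, 0.35, 0.018) and the intestine (7 higher and 3 lower of 15, the same over the list alone, median 0.35 but mean -0.09, 0.024). pals-24 rose by 3.02 ± 0.19 and asp-1 by 2.14 ± 0.16, while the metallothionein gene mtl-2 fell by 5.95 and cnc-4 fell by 2.32. The other lists were not called by camera. Their members higher and lower were 23 and 21 of 67 C-type lectins (adjusted p = 0.51), 9 and 7 of 22 lysozymes and saposin-like proteins (0.36), 24 and 32 cytochrome P450, UGT and GST enzymes with 63 not passing (0.51), and 2 and 2 of 15 DAF-16 class I targets (0.61). They were 3 and 0 of 12 heat shock proteins (0.53), 5 and 6 of 18 fatty acid metabolism genes (0.72), 0 and 1 of 6 vitellogenins (0.88), 2 and 0 of 17 sperm genes (0.39), and 0 and 3 of 11 pharynx genes (0.13). They were 2 and 5 of 15 pan-neuronal genes (0.39), 0 and 2 of 9 intraflagellar transport genes (0.72), 1 and 3 of 6 ciliated neuron signalling genes (0.24), and 2 and 0 of 11 mitochondrial messenger RNAs (0.51). Camera also called the pharynx list, with 8 genes lower (0.021, 0.48 with an estimated correlation), without che-3 PA14 replicate 1, which is outside this comparison. In that fit 7 neuropeptides were higher and 41 lower, the same over the list alone, 8 collagens were higher and 34 lower, 8 intestine genes were higher and 3 lower (11 and 3 over the list alone), 2 intraflagellar transport genes were higher and 2 lower, and 5 sperm genes were higher (0 over the list alone). Adjusted over the list alone, the counts were 26 and 23 C-type lectins, 10 and 7 lysozymes, 25 and 32 enzymes, 1 and 4 signalling genes, 0 and 2 pharynx genes, 1 and 0 mitochondrial messenger RNAs, 0 sperm genes, and unchanged counts for the 6 other lists named here. The median and mean differed in sign for C-type lectins (-0.09 and 0.23), DAF-16 targets (0.13 and -0.37), heat shock proteins (0.03 and -0.01), fatty acid metabolism (0.11 and -0.67) and vitellogenins (0.05 and -0.1).

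Infection of daf-10 also raised p38-dependent effectors and PMK-1-independent infection response genes and lowered acdh-1. irg-5 rose from 4.88 ± 0.725 to 343 ± 60.5 FPKM (6.14 ± 0.53, adjusted p = 1.39e-07), B0024.4 by 7.89 ± 0.56, C49G7.12 by 5.88 ± 0.25, C49G7.7 by 5.75 ± 0.37, Y47H9C.1 by 5.67 ± 0.78 and pgp-5 by 5.46 ± 0.20. acdh-1 fell from 570 ± 20.9 to 0.688 ± 0.159 FPKM (-9.68 ± 0.19, adjusted p = 2.9e-16), and acs-2 (-7.11), F18E3.12 (-5.08), ddo-2 (-5.03), amt-1 (-4.56) and the protease gene cpr-1 (-4.37) were also lower. irg-1 (4.91), irg-4 (3.17) and T24B8.5 (1.79) rose, and sod-3 (-0.77, adjusted p = 0.166) and hsp-16.2 (-0.38, 0.791) did not pass. Of the p38 effectors 13 of 13 were higher (median 3.2, camera adjusted p = 8.8e-21, adjusted p = 0.021 with an estimated correlation), and of the PMK-1-independent genes 6 of 7 (4.15, 1.6e-10, 0.015); adjusted over the list alone the counts were also 13 and 6. Of 67 collagens 3 were higher and 28 lower, 4 and 30 over the list alone (-0.66, 4.1e-06), and of 17 body wall muscle genes 9 were lower, 13 over the list alone (-0.51, 7.7e-06); 6 collagens were higher and 29 lower without che-3 PA14 replicate 1. With an estimated correlation these 2 lists lost their calls (adjusted p = 0.33 and 0.4), as did the 8 other lists called besides the effectors and PMK-1-independent genes (0.19 or more). edgeR called 0 of the 77 ribosomal protein genes in daf-10, as did limma and DESeq2, against 4 higher without che-3 PA14 replicate 1 and 3 with no filter, with 6 higher at an unadjusted p under 0.05 (median 0.16, camera adjusted p = 0.014, adjusted p = 0.95 with an estimated correlation). For the intestine the median was 0.50 and the mean -0.04. Of 25 caenacins and antimicrobial peptides limma called 0 higher and 8 lower, and of 67 C-type lectins 25 higher and 11 lower. In all, 921 genes were higher and 899 lower in infected daf-10.

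In che-3, infection raised C32H11.9 from 0.323 ± 0.306 to 105 ± 41.4 FPKM (8.29 ± 0.46, adjusted p = 5.59e-10). B0024.4 (6.50), irg-5 (6.46), C49G7.12 (5.68), pgp-5 (5.37) and clec-4 (5.11) followed, and irg-1 rose by 5.04 ± 0.43, T24B8.5 by 1.87 ± 0.24 and irg-4 by 1.46 ± 0.25. acdh-1 fell from 445 ± 60.1 to 0.224 ± 0.0696 FPKM (-10.98 ± 0.21, adjusted p = 2.48e-16), and acs-2 (-8.04), C09B8.4 (-5.84), cpr-1 (-5.41), mtl-2 (-5.41) and comt-4 (-5.14) were also lower. sod-3 was lower at -1.16 ± 0.37 (adjusted p = 0.0257), and hsp-16.2 did not pass (0.76, 0.417). The sod-3 call was lost without replicate 1, 2 or 3 of che-3 on OP50 (-1.15, -1.15 and -1.17) or replicate 3 of che-3 on PA14 (-1.17). The p38 effectors were higher in 13 of 13 (median 1.92, camera adjusted p = 3.5e-12, adjusted p = 0.11 with an estimated correlation) and the PMK-1-independent genes in 6 of 7 (3.87, 1.4e-08, 0.036), with the same counts adjusted over the list alone. Collagens were lower in 35 of 67, 37 over the list alone (-1.0, 1.3e-10), body wall muscle genes in 15 of 17, 15 over the list alone (-0.76, 1.2e-07), and DAF-16 targets in 6 of 15, 7 lower and 1 higher over the list alone (-1.15, 0.018). With an estimated correlation collagens (adjusted p = 0.11), muscle genes (0.29) and DAF-16 targets (0.29) lost their calls. Of the ribosomal protein genes 2 were higher, 6 lower and 69 did not pass, 0 over the list alone (-0.11, 0.29). Without che-3 PA14 replicate 1, 3 ribosomal protein genes were higher and 41 lower (-0.34, camera adjusted p = 1.2e-06), and C-type lectins (24 higher, 12 lower, 0.014) and lysozymes (11 and 4, 0.014) were called as well, and the median of the DAF-16 targets was -0.74, with 6 lower. None of these 3 lists passed with an estimated correlation (adjusted p = 0.75, 0.48 and 0.48), and the PMK-1-independent genes then no longer did (0.07). Without replicate 3 the ribosomal median was 0.04. Infection of che-3 gave 1612 genes higher and 1760 lower, 2005 and 2207 without che-3 PA14 replicate 1, and 545 and 794 with the compared groups alone.

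Of the genes higher in infected wild type, 766 were also higher in infected daf-10, where 194 would be shared if the calls were independent, and 727 were lower in both (184). With che-3, 911 were higher in both (339) and 989 lower in both (360). Across genes, the correlation of fold changes with those of wild type was 0.75 (Spearman 0.69) for daf-10 and 0.69 (0.57) for che-3; genes are not independent replicates. Opposite calls were 1 and 3 with daf-10 and 29 and 28 with che-3.

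**Figure D2:**
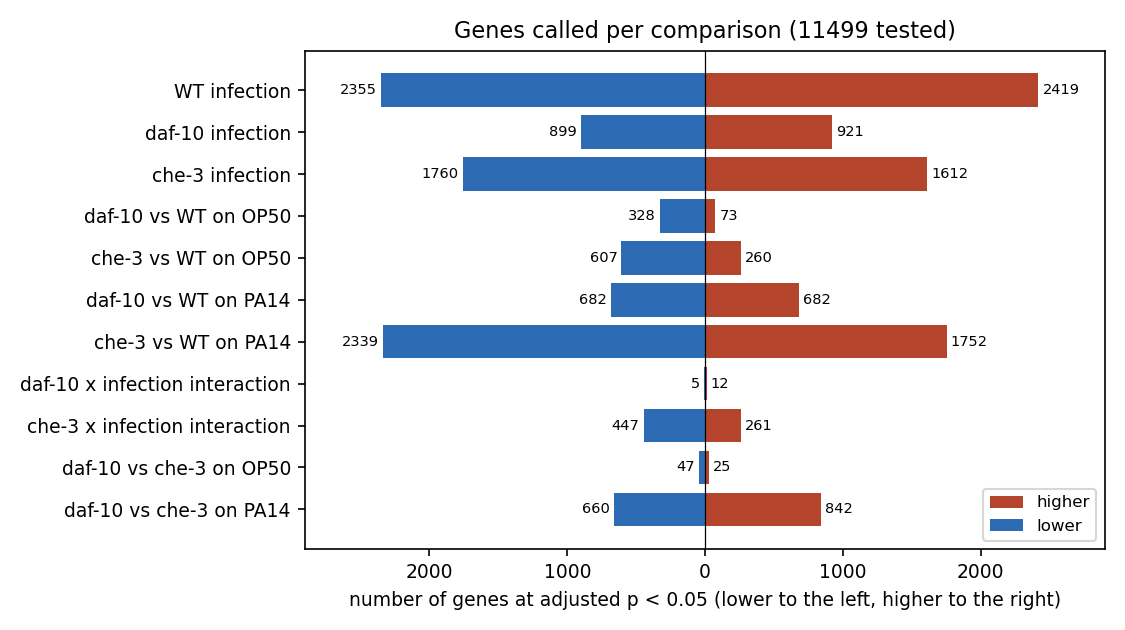
Number of genes called higher and lower in each of the 11 comparisons, edgeR adjusted p under 0.05, of 11499 genes tested. Infection of wild type gave the most calls (2419 and 2355) and the daf-10 interaction the fewest (12 and 5).

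Whether the mutants respond differently from wild type was tested by the interactions. In daf-10, C32H11.4 rose more on PA14 (26.9 ± 3.62 to 69.8 ± 12.2 FPKM in wild type, 16.9 ± 4.05 to 164.5 ± 12.4 in daf-10), a difference of 1.91 ± 0.35 (adjusted p = 0.0418). The C-type lectin gene clec-190 (1.81) and K07A1.6 (1.39) also had a positive difference, as did the p38 effector dod-24 (1.38 ± 0.25). cpt-5, which encodes a carnitine palmitoyltransferase, went from 5.75 ± 1.52 to 13.4 ± 2.46 FPKM in wild type and from 6.89 ± 1.48 to 2.19 ± 0.628 in daf-10 (-2.87 ± 0.43, adjusted p = 0.0178), and fbxb-46 (-2.55) and R02C2.1 (-2.42) were also negative. In all, 12 genes were higher and 5 lower, against 1910 at an unadjusted p under 0.05, and DESeq2 called 85 and 62, the fit of the compared groups alone 142 and 113, and that with no filter 334 and 286. The counts were 0 and 0 without replicate 2 of wild type on OP50, replicate 3 of wild type on PA14, or replicate 1, 2 or 3 of daf-10 on OP50. They were 0 and 1 without replicate 1 or 3 of wild type on OP50, 0 and 2 without daf-10 PA14 replicate 2, 5 and 2 without its replicate 3, and 31 lower without its replicate 1. Without wild-type PA14 replicate 1 they were 9 lower. Of the libraries outside this comparison, leaving out che-3 PA14 replicate 1 gave 228 and 308, and leaving out replicates 1, 2 and 3 of che-3 on OP50 gave 4 and 4, 2 and 3, and 7 and 5. The 6 genes with the largest differences all lost their calls without replicate 2 of wild type on OP50, replicate 3 of wild type on PA14, or any of the daf-10 OP50 libraries, and dod-24 did as well. clec-190 then ranged from 1.69 to 1.96 over all such fits, and cpt-5 from -3.13 to -2.7. clec-190, cpt-5 and R02C2.1 were called under every other setting tried.

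The che-3 interaction had 261 genes higher and 447 lower. E04D5.4 (2.52 ± 0.71, adjusted p = 0.0461), ZK402.3 (2.37) and the tubulin gene tbb-6 (1.86) were highest and T05A8.11 (-3.34), Y17D7B.2 (-3.08) and K10C2.14 (-3.06) lowest. tbb-6 fell from 9.53 ± 0.519 to 3.35 ± 0.717 FPKM in infected wild type and was 3.57 ± 0.726 and 4.63 ± 1.5 in che-3. The call of clec-4 (-1.61 ± 0.34, adjusted p = 0.0265) reflects a smaller induction in che-3. The counts depended on single libraries. They were 1606 and 1794 without che-3 PA14 replicate 1, 635 and 813 without wild-type PA14 replicate 1, and 0 and 0 without wild-type OP50 replicate 2 or wild-type PA14 replicate 3. They were 21 and 9 without wild-type OP50 replicate 1, 127 and 176 without its replicate 3, and 15 and 29 without wild-type PA14 replicate 2. Without che-3 OP50 replicate 1, 2 or 3 they were 17 and 36, 21 and 47, and 34 and 88, and without che-3 PA14 replicate 2 or 3 they were 31 and 21, and 54 and 24. Of the libraries outside this comparison, replicates 1, 2 and 3 of daf-10 on OP50 left 114 and 232, 112 and 212, and 146 and 198 when left out, and replicates 1 and 2 of daf-10 on PA14 left 167 and 152 higher. The 6 largest differences all lost their calls without replicate 1 or 2 of wild type on OP50, replicate 2 or 3 of wild type on PA14, replicate 1 or 3 of che-3 on OP50, or replicate 2 of che-3 on PA14. tbb-6 ranged from 1.73 to 2.12 over these fits, and clec-4 from -1.84 to -1.34 with its call lost in 6 of them. With only the 4 compared groups in the fit there were 0 and 1, against 3124 genes at an unadjusted p under 0.05 in the fit of all libraries, DESeq2 called 781 and 689, and the fit with no filter 617 and 796. With total counts the split moved to 1180 higher and 277 lower and the median of all genes by 0.172, and with median-ratio factors the split was 369 and 311.

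The median interaction of the ribosomal protein genes, which rose in infected wild type, was negative in both mutants. Both interactions subtract the same wild-type response, for this list and the others, so the results of the mutants are not independent. In che-3 59 of 77 were lower and 18 did not pass, 71 lower adjusted over the list alone (median -0.82, camera adjusted p = 4.6e-30, adjusted p = 0.66 with an estimated correlation); limma called 38, limma without a trend 9, DESeq2 67 and the fit of the compared groups alone 0. rpl-39 was at -1.40 ± 0.25, lost without replicate 1 or 2 of wild type on OP50 or replicate 3 of wild type on PA14. The count of 59 became 70 without che-3 PA14 replicate 1 and 1, 0 and 24 without replicates 1, 2 and 3 of wild type on OP50, 3 and 0 without replicates 2 and 3 of wild type on PA14, and 3, 9 and 10 without those of che-3 on OP50. It became 2 without replicate 2 or 3 of che-3 on PA14 and 35 without replicate 2 or 3 of daf-10 on OP50. The median of the list stayed negative in each of these fits, from -1.05 to -0.64. In daf-10 edgeR called 0 of 77, with 58 lower at an unadjusted p under 0.05, 55 adjusted over the list alone, 0 by limma, 9 by DESeq2, 19 with the compared groups alone, 59 with no filter and 50 without che-3 PA14 replicate 1 (-0.55, 1.9e-25, 0.59 with an estimated correlation). For the oocyte and eggshell genes the median interaction was positive. In che-3 4 of 21 were higher and 17 did not pass, with 12 over the list alone, 5 by limma, 8 by DESeq2 and 8 without che-3 PA14 replicate 1 (0.44, 1.1e-07, 0.66 with an estimated correlation). spn-4 was at 0.79 ± 0.14, lost without replicate 2 of wild type on OP50 or replicate 3 of wild type on PA14. In daf-10 edgeR called 0 of the 21, as did limma and DESeq2, with 9 higher at an unadjusted p under 0.05 (0.28, 4.4e-06, 0.59 with an estimated correlation). In wild type on PA14 the median deviations of the ribosomal list in the 3 libraries were 0.354, 0.537 and 0.725, and those of the oocyte list -0.082, -0.323 and -0.749. The estimated correlation removed all 9 list calls of the daf-10 interaction (adjusted p 0.59 or more) and all 4 of the che-3 interaction (0.66 or more). Without che-3 PA14 replicate 1, camera no longer called the PMK-1-independent genes in daf-10 (adjusted p = 0.059) or the intestine in che-3 (0.26). It then called the enzymes (0.032) and the pharynx (0.0088) in daf-10. In che-3 it called the enzymes (27 higher, 5 lower, 0.0098), germline genes (0.011), the pharynx (0.025), pan-neuronal genes (0.034) and neuropeptides (21 higher, 0.00034). None of these passed with an estimated correlation (adjusted p = 0.49 in daf-10 and 0.68 in che-3).

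**Figure D3:**
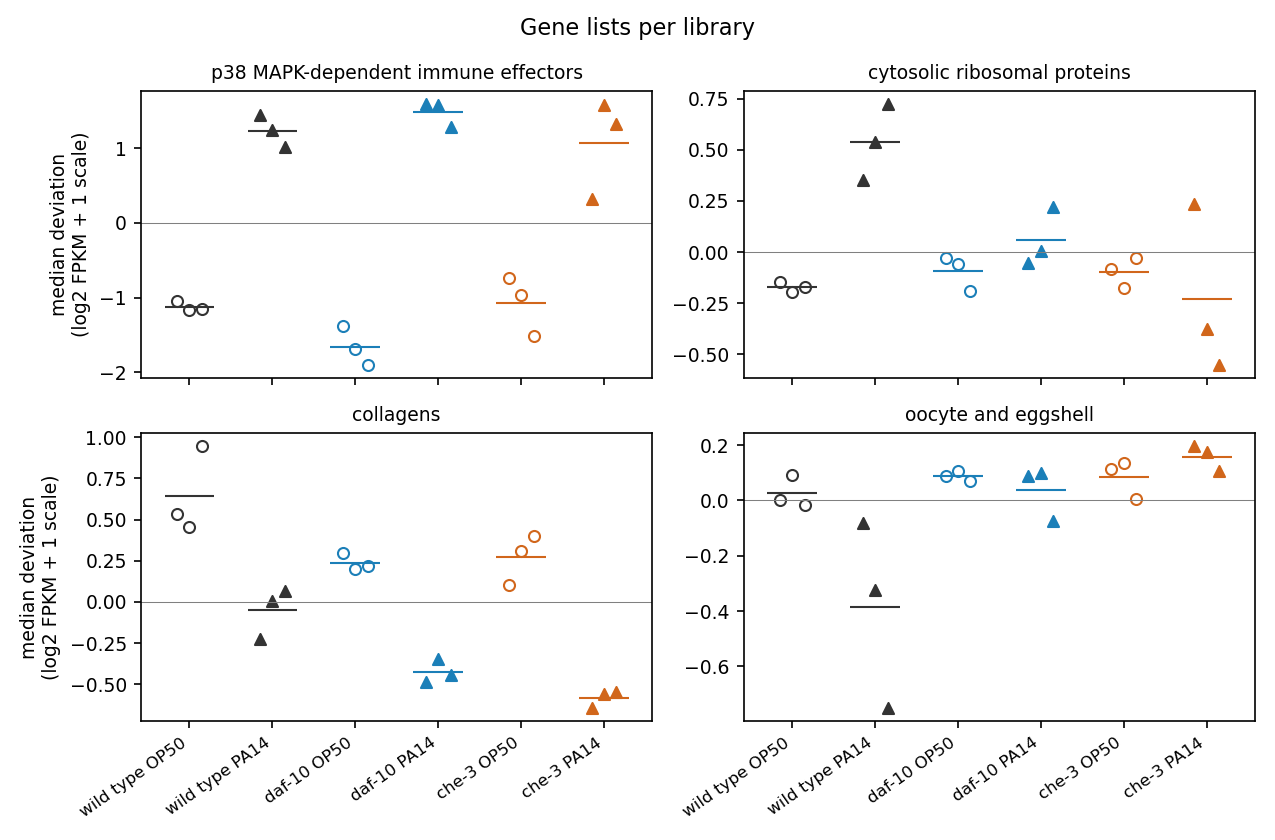
Median log2 deviation of p38 effectors, ribosomal proteins, collagens and oocyte genes in each library, a point per library. In wild type on PA14 the ribosomal medians are 0.354, 0.537 and 0.725, and those of the oocyte list -0.082, -0.323 and -0.749.

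Against wild type on OP50, the largest increase in daf-10 was that of F14D7.10. F14D7.10 (chromosome V, 14308464 to 14308856) was 20.6 ± 1.76 FPKM in daf-10 and 0.284 ± 0.145 in wild type (6.11 ± 0.74, adjusted p = 0.000318), and the nearby F14D7.7 was at 4.27 ± 0.68. W01C9.2 (3.66 ± 0.38), scl-25 (3.16), Y54G2A.15 (2.38) and scl-24 (2.21) were also higher; scl-25 (2.97 to 3.36) and scl-24 (1.99 to 2.38) lost their calls without any 1 of the 6 libraries, and Y54G2A.15 (1.65 to 2.82) without any wild-type library or daf-10 replicate 3. drd-10 (-3.69 ± 0.40), the neighbors nspc-17 (-3.50) and nspc-16 (-3.43), parg-2 (-3.43), K09C6.9 (-3.36) and Y41D4B.26 (-3.16) were lowest. lea-1, a DAF-16 target, rose from 101.8 ± 6.2 to 284 ± 49.7 FPKM (1.48 ± 0.14) and sod-3 by 1.82 ± 0.37, lost without wild-type replicate 3 (1.77) or daf-10 replicate 1 (1.62), and fat-7, which encodes a fatty acid desaturase, was lower at -2.43 ± 0.46. Of the p38 effectors 0 were higher and 4 of 13 lower, 1 and 5 over the list alone (median -0.16, camera adjusted p = 0.038), with C17H12.8 at -1.71 ± 0.38 (lost without daf-10 replicate 2 or 3, range -1.94 to -1.48). With an estimated correlation none of the 9 list calls of this comparison remained (adjusted p 0.81 or more). Of 67 collagens 5 were lower, 9 over the list alone (-0.36, 4.4e-05), and of 15 DAF-16 targets 2 were higher and 1 lower, 3 and 1 over the list alone (0.33, 0.0092). edgeR called 0 of 12 heat shock proteins, as did limma and DESeq2, with 6 lower at an unadjusted p under 0.05 (-1.61, 0.0084). There were 73 genes higher and 328 lower, 407 and 913 with the compared groups alone, 158 and 667 with no filter, and 141 and 516 by DESeq2. Without replicates 1, 2 and 3 of wild type there were 26, 42 and 40 higher, and 32, 27 and 31 without those of daf-10; lower genes numbered 184 without replicate 1 of wild type, 155 without its replicate 3, and 184, 132 and 160 without replicates 1, 2 and 3 of daf-10. There were 175 higher and 573 lower without che-3 PA14 replicate 1, which is outside this comparison, and the lysozymes lost their list call (adjusted p 0.048 to 0.057). In that fit 1 p38 effector was higher and 5 lower, 1 collagen was higher and 12 lower (1 and 17 over the list alone), and 2 heat shock proteins were lower (7 over the list alone).

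On OP50, more genes were called against wild type in che-3 than in daf-10. F14D7.10 (6.14 ± 0.74), F14D7.7 (4.12 ± 0.68) and W01C9.2 (3.90 ± 0.38) were higher again. osm-6, which encodes a protein of an intraflagellar transport complex (chromosome V, 11924632 to 11927406), was 14.5 ± 1.69 FPKM against 0.3 ± 0.146 (5.58 ± 0.57, adjusted p = 1.64e-05). unc-36, which encodes a calcium channel subunit, was 34.7 ± 2.72 against 1.66 ± 0.0551 FPKM (4.39 ± 0.27, 3.33e-08), and C08F11.7 was at 4.72 ± 0.32. The lipase gene lipl-5 (chromosome V, 385713 to 388090) fell from 203 ± 13.6 to 5.56 ± 3.58 FPKM (-5.18 ± 0.31, adjusted p = 3.15e-08), followed by nspc-16 (-3.43), Y48E1B.8 (-3.26), Y69A2AR.12 (-3.12), nspc-17 (-3.12) and nspc-18 (-2.99). lea-1 rose by 1.56 ± 0.14 and clec-190 by 2.41 ± 0.19, and fat-7 was at -1.71 ± 0.43, lost without wild-type replicate 1 or 3 or che-3 replicate 2 or 3 (range -1.94 to -1.49). Of 6 ciliated neuron signalling genes ttx-1 (-1.0 ± 0.26) and daf-7 (-0.87 ± 0.25) were lower, 2 also over the list alone (camera adjusted p = 0.11); both calls were lost without any 1 of the 6 libraries, with ranges of -1.12 to -0.83 and -1.03 to -0.75. Of the vitellogenins 3 of 6 were lower, 3 over the list alone (median -0.36, camera adjusted p = 0.028), of the collagens 1 was higher and 10 lower, 1 and 12 over the list alone (-0.22, 0.028), and of the DAF-16 targets 2 were higher, 3 over the list alone (0.40, 0.011). None of the 9 list calls remained with an estimated correlation (adjusted p 0.45 or more). edgeR, limma and DESeq2 called 0 heat shock proteins, with 5 lower at an unadjusted p under 0.05 (-1.33, 0.028). In all, 260 genes were higher and 607 lower, 537 and 1028 with the compared groups alone, and 317 and 913 with no filter. Without replicates 1, 2 and 3 of wild type there were 98, 162 and 108 higher, and without replicates 1 and 3 of che-3 131 and 116; 360 and 288 were lower without replicates 1 and 3 of wild type, and 308 and 342 without those of che-3. When che-3 PA14 replicate 1, outside this comparison as well, was left out, 485 were higher and 943 lower, and the mitochondrial messenger RNAs lost their list call (adjusted p 0.043 to 0.051). Then 2 collagens were higher and 15 lower (4 and 17 over the list alone), 2 heat shock proteins were lower (6), and 1 signalling gene was higher and 3 lower over the list alone.

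Of these genes on OP50, 48 were higher and 231 lower in both mutants, where 1.65 and 17.3 would be shared if the calls were independent, and 0 were called in opposite directions. The counts were 96 and 375 (7.38 and 47 if independent), with 4 opposite, without che-3 PA14 replicate 1. The correlation of the fold changes across genes was 0.65, against a mean of 0.488 in 10 simulations of unchanged mutants. The covariance was 0.184, against 0.0433 in the simulations. These drew all 18 libraries anew and compared both mutants with the same simulated wild type. Genes were drawn independently, so shifts that many genes share within a real library are absent. The excess therefore cannot tell an effect shared by the mutants from shifts in the wild-type libraries that both are compared with.

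In che-3 the genes next to unc-36 were high as well. In the fit without a filter unc-36 (WBGene00006772, chromosome III, 8193844 to 8201206) was at 4.37 ± 0.14, and C30A5.10 (8205124 to 8209945) was 10.5 ± 0.589 FPKM against 0.0313 ± 0.0428 in wild type (8.35 ± 0.34). Between them lie the noncoding RNA gene C50C3.15 and the synaptobrevin gene snb-5, which had 0 counts in every wild-type and daf-10 library. Against a floor of 3 counts over the wild-type group, C50C3.15 was at least 61-fold higher in che-3 on OP50 and at least 67.8-fold on PA14, and snb-5 at least 13.5-fold and 20.8-fold. The flanking genes C50C3.1 (0.14 ± 0.11) and unc-86 (-0.74 ± 0.48) did not pass in che-3, nor did unc-36 in daf-10 (-0.06 ± 0.15). On PA14 unc-36 was at 4.60 ± 0.14 and osm-6 at 5.41 ± 0.30 in che-3 in the same fit. The values of genes near osm-6 are from that fit as well. F58H1.2 (11929073 to 11929993) was also higher in che-3, at 2.22 ± 0.48 on OP50 (adjusted p = 0.000282) and 2.32 ± 0.45 on PA14. R31.2, on the other side, did not pass on either food (0.01 and 0.09), and aman-2, whose span holds F58H1.2, did not pass on OP50 (0.21 ± 0.09) and was at 0.49 ± 0.09 (adjusted p = 5.77e-06) on PA14.

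**Figure D4:**
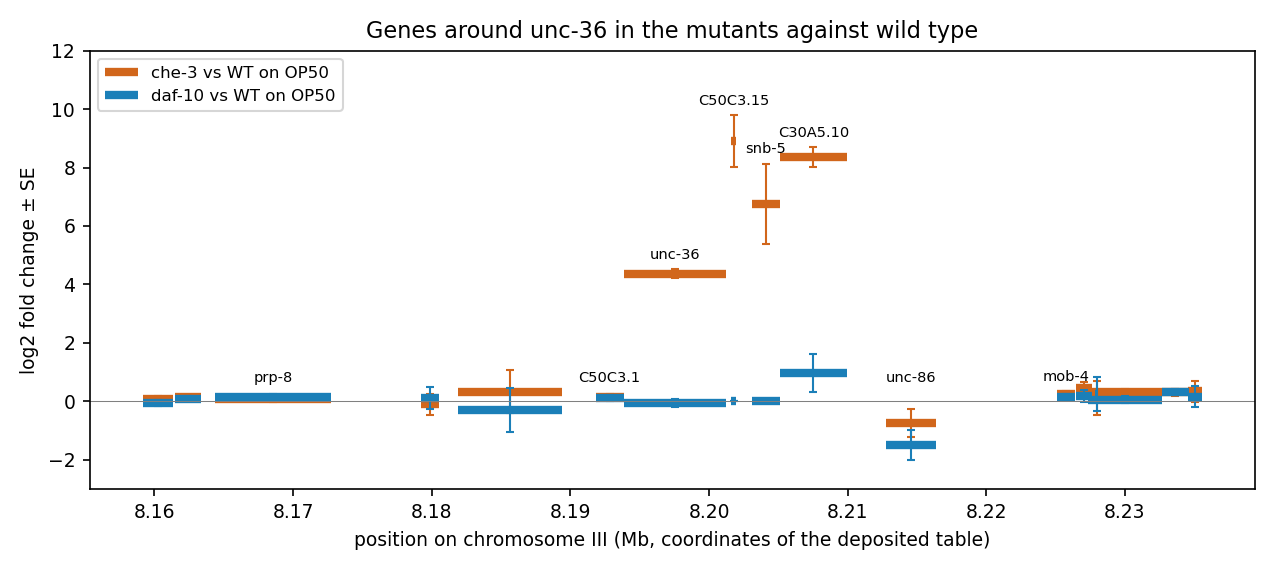
Log2 fold change against wild type on OP50 (± SE) of genes on chromosome III around unc-36, for che-3 and daf-10, by position. The 4 genes from unc-36 to C30A5.10 are high in che-3, with C50C3.1 at 0.14 and unc-86 at -0.74 on either side.

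On PA14, F14D7.10 (6.31 ± 0.76, adjusted p = 0.000168) was again highest in daf-10 against wild type. icmt-1 was 11.4 ± 3.81 FPKM against 0.509 ± 0.443 (4.47 ± 0.57, adjusted p = 0.000256), and scl-24 (4.40), F14D7.7 (3.52), W01C9.2 (3.44) and F46A9.1 (3.27) were higher. nspc-16 (-4.56 ± 0.56), fat-7 (0.886 ± 0.612 against 18.3 ± 4.44 FPKM, -4.34 ± 0.41) and F09C8.1 (-3.78 ± 0.26) were lower. The sperm genes spch-1 (-5.02), msp-31 (-3.91) and msp-33 (-3.68) were also called lower, but all lost their calls without wild-type replicate 2 or any daf-10 library on PA14, and msp-33 also without wild-type replicate 3. Without wild-type replicate 2 they were at -1.08, -0.97 and -1.42. irg-5 (2.0 ± 0.42, lost without wild-type PA14 replicate 3) and irg-4 (1.55 ± 0.24) were higher and clec-4 (-1.15 ± 0.18) lower, so that 2 of 13 p38 effectors were higher and 1 lower, 3 and 1 over the list alone (median 0.25, camera adjusted p = 0.17). Of the ribosomal proteins 40 of 77 were lower, 64 over the list alone (-0.47, 8.9e-20), 23 by limma and 48 by DESeq2. None of the 6 list calls remained with an estimated correlation (adjusted p 0.81 or more). The 40 became 26 without wild-type OP50 replicate 1, 16 and 6 without wild-type PA14 replicates 2 and 3, 9 without daf-10 PA14 replicate 1 or 2, and 70 without che-3 PA14 replicate 1. Of 21 oocyte and eggshell genes 12 were higher, 18 over the list alone (0.38, 1e-09), and of the heat shock proteins 3 of 12 were lower, 3 over the list alone (-1.12, 0.0015). There were 682 genes higher and 682 lower, 1151 and 427 with total counts, 410 and 455 with the compared groups alone, and 1026 and 1179 with no filter. Without replicates 2 and 3 of wild type on PA14 there were 340 and 312, and 138 and 110, and without replicates 1 and 2 of daf-10 252 and 269, and 182 higher and 0.204 times the 682 lower. Leaving out che-3 PA14 replicate 1, outside this comparison, gave 1299 and 1372; camera then called the pharynx (adjusted p = 0.042, 0.66 with an estimated correlation) and no longer the collagens (0.07) or the vitellogenins (0.058). Of the p38 effectors 5 were then higher and 2 lower, and of the heat shock proteins 6 were lower (9 over the list alone).

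Against wild type on PA14, F14D7.10 (6.55 ± 0.76), osm-6 (5.40 ± 0.55), unc-36 (4.59 ± 0.28), icmt-1 (4.48 ± 0.57), scl-24 (4.33 ± 0.70) and W01C9.2 (4.14 ± 0.37) were highest in che-3 among genes above 0 FPKM in every library of both groups. C30A5.10, with 0 FPKM in a wild-type library, was at 8.51 ± 0.34 in the fit without a filter. lipl-5 was 3.07 ± 0.307 FPKM against 117 ± 4.6 (-5.28 ± 0.33, adjusted p = 3.06e-08), and nspc-18 (-3.38), fat-7 (-3.37), C27A7.8 (-3.37), nspc-16 (-3.28) and fbxb-11 (-3.24) were lowest; the call of fbxb-11 was lost without wild-type PA14 replicate 2 (-2.71). irg-1 was lower in che-3 at -1.46 ± 0.29 and clec-4 at -1.28 ± 0.18, and lea-1 was higher at 1.37 ± 0.14. Of the p38 effectors 1 was higher and 2 lower, the same over the list alone (median -0.15, camera adjusted p = 0.88), and 5 and 2 without che-3 PA14 replicate 1 (0.09, 0.52). Of the ribosomal proteins 1 was higher and 69 lower, 2 and 69 over the list alone (-0.75, 1.6e-17), with 65 lower by limma, 69 by DESeq2 and 25 with the compared groups alone. None of the 5 list calls remained with an estimated correlation (adjusted p 0.84 or more). Of 21 oocyte and eggshell genes 18 were higher, 18 over the list alone (0.48, 1.5e-08), with chs-1 at 0.79 ± 0.12. Of the vitellogenins 5 of 6 were lower, 6 over the list alone (-0.52, 0.0044), of the collagens 2 were higher and 28 lower, 3 and 30 over the list alone (-0.84, 0.00039), and of 15 intestine genes 5 were lower, 5 over the list alone (-0.29, 0.025). Without che-3 PA14 replicate 1, camera no longer called collagens (14 higher, 29 lower, 16 and 31 over the list alone, adjusted p = 0.1) or the intestine (0.2) but called neuropeptides (33 higher, 5 lower, 0.00065, against 11, 11 and 0.59, and 0.94 with an estimated correlation). There were 1752 genes higher and 2339 lower, with 1518 and 1506 lower without che-3 PA14 replicates 2 and 3. The compared groups alone gave 733 and 579. Total counts gave 2909 and 1369 and moved the median of all genes by 0.162. Shared with daf-10 were 474 higher (103.9 if independent) and 550 lower (138.7), 938 and 1079 without che-3 PA14 replicate 1, and 5 were opposite (27 without it). The correlation across genes was 0.7 against a mean of 0.525 in the simulations, with the same limit as on OP50.

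daf-10 and che-3 animals were also compared directly. On OP50 lipl-5 was 163 ± 39.5 FPKM in daf-10 and 5.56 ± 3.58 in che-3 (4.87 ± 0.31, adjusted p = 7.27e-08), and pgp-6 (2.47) and C46G7.5 (2.25) were also higher in daf-10; the call of pgp-6 was lost without replicate 2 or 3 of che-3 (2.55 and 1.95) or of daf-10 (2.37 and 2.45). C30A5.10 (-7.40 ± 0.58), osm-6 (-5.07 ± 0.54) and unc-36 (-4.44 ± 0.27) were lower in daf-10. clec-190 (-2.0 ± 0.19) and the glutathione transferase gene gst-4 (-2.78 ± 0.43) were lower in daf-10 as well. There were 25 genes higher and 47 lower, 256 and 151 with the compared groups alone, 196 and 217 with no filter, and 131 and 134 by DESeq2. Higher genes numbered 14, 16 and 8 without replicates 1, 2 and 3 of che-3 and 11, 9 and 15 without those of daf-10; lower genes numbered 28 without replicate 3 of che-3 and 26, 22 and 23 without those of daf-10. Leaving out che-3 PA14 replicate 1, outside this comparison, gave 111 higher and 2.96 times the 47 lower. Among 6 lists called, edgeR called 0 of the 13 p38 effectors, as did limma, against 2 by DESeq2, 4 lower without che-3 PA14 replicate 1 and 6 lower at an unadjusted p under 0.05 (median -0.44, camera adjusted p = 0.0034, adjusted p = 0.75 with an estimated correlation); 5 were lower adjusted over the list alone, and 2 higher and 6 lower without that library.

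On PA14 lipl-5 (128 ± 3.24 against 3.07 ± 0.307 FPKM, 5.41 ± 0.33, adjusted p = 3.64e-08), Y49G5A.1 (3.40) and C46G7.5 (3.39) were higher in daf-10 than in che-3, and osm-6 (-5.60), unc-36 (-4.49) and F59C6.18 (-4.02) lower. The call of Y49G5A.1 was lost without daf-10 PA14 replicate 3 (2.62), and that of F59C6.18 with the compared groups alone. irg-4 (1.42 ± 0.24) and dod-24 (1.02 ± 0.17) were higher in daf-10, so that 2 of 13 p38 effectors were higher, 4 over the list alone (median 0.16, camera adjusted p = 0.039). The 10 list calls became 0 with an estimated correlation (adjusted p 0.88 or more) and 1 without che-3 PA14 replicate 1, the ribosomal proteins (adjusted p = 1.2e-14, 0.94 with an estimated correlation); in that fit 2 p38 effectors were higher and 1 lower, 2 and 2 over the list alone. daf-7, which encodes a TGF-beta ligand of sensory neurons, was 1.32 ± 0.304 FPKM in daf-10 and 0.562 ± 0.0567 in che-3 (1.25 ± 0.27), a call lost without daf-10 PA14 replicate 2 (range 1.04 to 1.38). Of the ribosomal proteins 14 were higher and 5 lower, 27 and 6 over the list alone (0.30, 0.0021), and with the compared groups alone 0 and 0, against 12 and 5 by limma and 20 and 5 by DESeq2. The median was 0.50, 0.18 and 0.14 without che-3 PA14 replicates 1, 2 and 3. The 14 became 47, 3 and 3 without these, 6, 4 and 6 without those of daf-10, and 8 without wild-type OP50 replicate 1, and of 15 intestine genes 6 were higher, 8 over the list alone (0.32, 0.012). There were 842 genes higher and 660 lower, 541 and 1117 with total counts, and 27 and 10 with the compared groups alone. Without che-3 PA14 replicate 1 there were 1614 and 1258, without its replicate 2 516 higher, without its replicate 3 323 and 419, and without daf-10 PA14 replicates 1 and 2 394 and 316, and 325 and 230.

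At an adjusted p under 0.05, the authors' deposited table gave 2553 genes higher and 2543 lower in infected wild type, 1116 and 1343 in infected daf-10, and 984 and 1017 in infected che-3. Against wild type on OP50, the authors' deposited table gave 448 and 943 in daf-10 and 600 and 1122 in che-3, and on PA14 706 and 822 in daf-10 and 924 and 938 in che-3. Every gene called here in these 7 comparisons had the same sign in the authors' deposited table. Of the genes called here, those also under 0.05 in the authors' deposited table were 4290 of 4774 in infected wild type, 1717 of 1820 in infected daf-10 and 1868 of 3372 in infected che-3. For each mutant against wild type, daf-10 then che-3, those in the authors' deposited table were 393 of 401 and 829 of 867 on OP50, and 1028 of 1364 and 1767 of 4091 on PA14.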

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

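The tests of admixture, of age and of the unc-36 segment were chosen only after the result was seen, as was the division of the interaction splits by whether both foods were mixed; the tests of gene length, of the ribosomal proteins and the count of splits were not.

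In the fit of all 18 libraries, the interaction tests called genes for both mutants. For daf-10, 12 genes were higher and 5 lower: among them C32H11.4 (1.91), clec-190 (1.81) and K07A1.6 (1.39), and cpt-5 (-2.87), fbxb-46 (-2.55) and R02C2.1 (-2.42). For che-3, 261 were higher and 447 lower: among them E04D5.4 (2.52), ZK402.3 (2.37) and tbb-6 (1.86), and T05A8.11 (-3.34), Y17D7B.2 (-3.08) and K10C2.14 (-3.06). By camera, the lists that differed in daf-10 were the p38 effectors (median 0.84), the PMK-1-independent genes (-0.75), C-type lectins (0.29), the hypoxia response (0.43), vitellogenins (-0.27), oocyte genes (0.28), germline genes (-0.21), neuropeptides (0.61) and ribosomal proteins (-0.55). In che-3 they were the hypoxia response (0.55), oocyte genes (0.44), the intestine (-0.25) and ribosomal proteins (-0.82). With an estimated correlation between genes, 0 of these lists passed. The counts of genes were 228 and 308 for daf-10 and 1606 and 1794 for che-3 without che-3 PA14 replicate 1, and the PMK-1-independent genes in daf-10 (adjusted p = 0.059) and the intestine in che-3 (0.26) lost their calls. Without wild-type OP50 replicate 2 or wild-type PA14 replicate 3 the counts of genes were 0 for both.

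Splits of the libraries into genotypes within each food were compared for each interaction: the real split and 59 others drawn at random from those possible. Of these 60, counting the real split, 3 called at least as many genes as the real daf-10 interaction (17, highest of the others 31). For che-3, 6 called as many as the real interaction (708, highest of the others 2223), so chance is not excluded for either. The highest count for each mutant came from a split that left the genotypes of 1 food unmixed. All of the other splits as large, 2 for daf-10 and 5 for che-3, left the genotypes of 1 food unmixed, as 13 and 12 of the splits do. Such a split carries the genotype difference on that food into the contrast, so it is no measure of chance for the interaction. With both foods mixed, 0 of 46 and 0 of 47 splits were as large, and the highest count was 0 in each. Mixing puts the genotype differences into the spread, which lowers these counts, so they cannot exclude chance.

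Ribosomal protein genes rose on PA14 in wild type, and the median interaction of the list was negative in both mutants. Both interactions subtract that same wild-type rise, so the mutants do not support each other independently. The scaling of the libraries is argued against, since with total counts the median che-3 interaction of the list was still -0.65. A trend of short and abundant transcripts remains open: 62 genes picked as nearest in length and level had a median of 0.26 (quartiles -0.02 to 0.65) against 0.71 (0.68 to 0.75), a share of 0.36, but their median level was 819 FPKM against 1740, so level was not matched. A genotype-dependent growth response may be behind it, but the 3 wild-type PA14 libraries spread from 0.354 to 0.725, and the stage of the animals at collection is not given per library in the sources used here.

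Replicate 1 of che-3 on PA14 stood apart from the other libraries of its group. A trend with gene length is argued against for this library by a correlation of 0.02 across genes with its deviation. Elsewhere the same correlation reached -0.28 (daf-10 PA14 replicate 2), 0.27 (daf-10 OP50 replicate 3) and -0.25 (wild-type OP50 replicate 1), so length trends in other libraries are not excluded. Animals younger than adults are argued against by vitellogenins at a median of 0.03 relative to the other libraries of the group. Admixture of wild-type RNA is argued against as the whole cause by the gene lists: of 6 that deviated, 5 lay outside the range of the other che-3 and the wild-type PA14 libraries, such as the p38 effectors at 0.31 against 1.01 to 1.58, and 4, not the p38 effectors, also with the wild-type OP50 libraries added. As a part of the cause admixture remains open: the median share it would need was 53.9% over 48 genes higher in che-3 on OP50 (quartiles 5.7% to 85.2%; unc-36, 19.9 FPKM against 43.6 and 49.2 in the other libraries, is one), but 10.4% over 84 lower genes (-0.6% to 25.3%) and -6.11% over the 4 lowest (-14.6% to 39.9%). Of these 4, lipl-5 was the most abundant in wild type on PA14 (117 FPKM) and implied a share of 0.464%. The others, at 5.27 to 10.7 FPKM, implied -14.6% (nspc-17), -12.7% (nspc-16) and 39.9% (parg-2). Handling of the sample may explain the library but was not tested. Apart from the age of the animals, no biological explanation was tested.

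The genes from unc-36 to C30A5.10 on chromosome III, and osm-6 on chromosome V, were high in che-3. A response shared by mutants without intact cilia is argued against by unc-36 in daf-10, at -0.06 against wild type. A run of 4 adjacent genes was at least 2-fold higher, which extra copies of that segment in the che-3 strain would give. Genes with few counts were skipped in drawing it. The run was extended from unc-36 until a gene did not pass, so flanking genes that were not higher follow from its drawing and are no support. The flank unc-86 had a mean of only 28 counts in wild type and 16.7 in che-3 on OP50. Near osm-6, F58H1.2 was also high on OP50 (2.22) while R31.2 (0.01) and aman-2 (0.21) did not pass. How far a second segment would reach was not tested. The test asked only for a 2-fold rise. On OP50 the log2 fold changes were 4.37 for unc-36 and 8.35 for C30A5.10, and C50C3.15 and snb-5 were at least 61-fold and 13.5-fold higher. These sizes argue against a duplication that only doubles the copies. Copies may come from an inserted transgene or a larger multiplication, and reads across a junction, which would tell, were not analysed here. A change in regulation of this stretch in che-3 alone remains open as the biological alternative.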

How the results depend on the processing

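Total counts, the count filter, DESeq2 and the runs of lists and overlaps without che-3 PA14 replicate 1 were chosen only after the data were seen, and limma on log2(FPKM + 1), the planned test, became an alternative then; lists and overlaps were not rerun without the other libraries. No named gene changed sign where either value was called, without a library of the compared groups or under the other settings. Of the lists, the cytochrome P450, UGT and GST enzymes for daf-10 against che-3 on PA14 turned from direction 1 to -1 and lost their call without che-3 PA14 replicate 1 (adjusted p 0.027 to 0.74); the cause was not tested. Which of higher and lower genes was more numerous changed with the scaling, with total counts for the 3 infections, che-3 on PA14, the che-3 interaction and daf-10 against che-3 on PA14, and with median-ratio factors for the same except che-3 on PA14. It also changed under other settings, with the compared groups alone for infection of wild type and daf-10, che-3 on PA14 and daf-10 against che-3 on OP50, and for the 3 infections, the che-3 interaction and daf-10 against che-3 on PA14 with DESeq2 and with limma on log2(FPKM + 1). With no replicate left out it changed under none for daf-10 and che-3 against wild type on OP50. Infection of wild type, daf-10 and che-3 kept counts within 1.5 times those reported in every fit without 1 of the 18 libraries; each of the other 8 comparisons had a count that did not. For single named genes, 3550 values without 1 library were on the same side of the threshold, 1028 no longer passed and 12 newly passed; under the other settings these were 6938, 500 and 17. In 0 of 15 pairs of groups did every pair of libraries with the same number correlate above 0.1 (range -0.2 to 0.26), so the numbers were not taken to pair the libraries. In 3 of them each library correlated best with its own number, a hint from the data: che-3 on OP50 and PA14 (0.1, 0.08 and 0.09, others at most 0.01), daf-10 on OP50 and PA14 (0.05, 0.08 and 0.02, at most 0), and wild type on OP50 with che-3 on PA14 (0.13, 0.04 and 0.11, at most 0.06). At 18550309 counts or more per library, most cilia genes stayed below the filter. The cause was not tested for the changes below, except that a 2-fold limit and fewer or more tested genes change counts by construction. A library outside a comparison can move its counts only through the spread and the scaling, which are estimated over all libraries.

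Counts are given as higher and lower, or 1 of them where only that moved. A 2-fold limit gave 628 and 724 for infection of wild type, 515 and 440 for daf-10, and 432 and 595 for che-3. Against wild type it gave 38 and 187 (daf-10) and 90 and 214 (che-3) on OP50, and 108 and 170, and 200 and 490, on PA14. It left 5 higher for the daf-10 interaction, 27 and 128 for the che-3 interaction, 8 higher for daf-10 against che-3 on OP50 and 114 and 64 on PA14, and overlaps of the mutants of 24 and 106 on OP50 and 50 and 118 on PA14. Total counts gave 1499 higher for infection of wild type, 1151 and 427 (daf-10) and 2909 and 1369 (che-3) on PA14, 28 higher and 1180 and 277 for the daf-10 and che-3 interactions, and 541 and 1117 for daf-10 against che-3 on PA14. A mean FPKM of at least 5 gave 589 and 576 for infection of daf-10, 41 and 194 (daf-10) and 155 and 389 (che-3) on OP50, 7 and 1 and 508 higher for the interactions, and 15 and 18 for daf-10 against che-3 on OP50. No filter on low values gave 158 and 667 (daf-10) and 913 lower (che-3) on OP50, 1026 and 1179 for daf-10 on PA14, 334 and 286 and 617 and 796 for the interactions, and 196 and 217 for daf-10 against che-3 on OP50. Libraries of the compared groups only gave 545 and 794 for infection of che-3, 407 and 913 (daf-10) and 537 and 1028 (che-3) on OP50, 410 higher (daf-10) and 733 and 579 (che-3) on PA14. They gave 142 and 113, and 0 and 1, for the interactions, and 256 and 151 on OP50 and 27 and 10 on PA14 for daf-10 against che-3.

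DESeq2 gave 141 and 516 for daf-10 on OP50, 85 and 62 and 781 and 689 for the interactions, and 131 and 134 on OP50 and 1023 lower on PA14 for daf-10 against che-3. For the daf-10 interaction the replicate block gave 7 higher, limma on log2(FPKM + 0.1) 1 and 3, limma without a mean-variance trend 2 higher, and limma on log2(FPKM + 1) 9 lower. For the che-3 interaction limma on log2(FPKM + 0.1) gave 201 lower, limma without a trend 122 and 78, limma on log2(FPKM + 1) 400 and 279, and the count filter 160 and 296; limma without a trend gave 42 higher for daf-10 against che-3 on OP50. With an estimated correlation, camera called 2 lists for infection of daf-10, 1 for che-3 and 0 for the other 9 comparisons; on TMM-scaled log2 CPM it called 5 for daf-10 against che-3 on PA14.

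Without 1 library of the compared groups, the ranges were 1698 to 2327 and 1742 to 2280 for infection of wild type, 702 to 795 and 640 to 783 for daf-10, and 1148 to 2005 and 1261 to 2207 for che-3. On OP50 they were 26 to 42 and 132 to 291 for daf-10, and 98 to 178 and 288 to 494 for che-3; on PA14 138 to 975 and 110 to 933, and 1279 to 2508 and 1506 to 2751. For the interactions they were 0 to 17 and 0 to 31, and 0 to 1606 and 0 to 1794, and for daf-10 against che-3 8 to 16 and 22 to 38 on OP50 and 323 to 1614 and 230 to 1258 on PA14. For comparisons it is no part of, che-3 PA14 replicate 1 left out gave 175 and 573 (daf-10) and 485 and 943 (che-3) on OP50, 1299 and 1372 for daf-10 on PA14, 228 and 308 for the daf-10 interaction, and 111 higher and 2.96 times as many lower for daf-10 against che-3 on OP50. Other libraries outside a comparison moved counts more than 1.5-fold only for the interactions, to 2 to 7 higher for daf-10 without 1 of the che-3 OP50 libraries and 3 lower without replicate 2 of these, and for che-3 to 112 to 167 higher without 1 of the daf-10 libraries other than PA14 replicate 3 and 198 to 232 lower without 1 of the daf-10 OP50 libraries. Without che-3 PA14 replicate 1 there were 10 lists for infection of che-3, 4 for che-3 on PA14, 8 for its interaction and 1 for daf-10 against che-3 on PA14, and overlaps of 96 and 375 on OP50 and 938 and 1079 on PA14.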

Other observations

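The test of the propionate genes was chosen only after the fall of acdh-1 and the values of these genes were seen, so its outcome is no independent support. The tests of linkage to the mutated genes and the counts of splits were chosen before.

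The fall of acdh-1 on PA14 may reflect vitamin B12 supplied by PA14, since B12 is known to repress the propionate shunt. Of hphd-1, hach-1, ech-6 and alh-8 of the shunt, 4 were lower in infected wild type (-4.74, -1.34, -1.89 and -1.05), and they were called lower in daf-10 (-4.36, -1.44, -1.68 and -1.21) and che-3 (-4.05, -1.13, -1.87 and -1.0) as well. B12 itself was not measured, and infection and the change of food cannot be separated in these groups.

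Genes called on OP50 did not gather around the mutated genes, as variants linked to them would give. Within 2 Mb of daf-10, 21 of 588 tested genes were called in daf-10, 3.57% against 3.48% elsewhere (ratio 1.03), and within 2 Mb of che-3, 31 of 644 in che-3, 4.81% against 7.7% (0.63).

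The groups of 3 libraries allow 10 splits, too few for a share under 0.05; in each comparison of 2 groups the real split, 1 of 10, had the most calls. The real count and the highest of the other splits were 4774 and 0 for infection of wild type, 1820 and 0 for daf-10, and 3372 and 21 for che-3. They were 401 and 0 for daf-10 and 867 and 0 for che-3 against wild type on OP50, and 1364 and 98, and 4091 and 1377, on PA14. For daf-10 against che-3 they were 72 and 0 on OP50 and 1502 and 527 on PA14.

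Over 1497 genes called in both infected wild type and infected daf-10, the slope of each PA14 library's response on the wild-type response was 0.97, 0.91 and 0.98 in wild type, 0.9, 0.88 and 0.92 in daf-10, and 0.85, 0.83 and 0.79 in che-3. The choice favors genes with large measured effects in wild type and daf-10, so the che-3 slopes are not comparable with theirs. The wild-type response was estimated from the same wild-type libraries, so their slopes are high by construction and are no reference for either mutant.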
